A study of Mus musculus with 11 samples.

How the data were processed

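RNA was measured by sequencing in 11 libraries of mouse soleus and quadriceps, hindlimb muscles, from animals 2.5 months old. Per the labels, 1 set of animals carried a doxycycline-inducible Myc system, received doxycycline overnight and was sampled 12 hours after the drug was withdrawn, and age-matched animals were the controls. The labels do not say whether the controls received doxycycline or what their genotype was. Libraries were grouped by title into soleus control (3), soleus Myc (4), quadriceps control (2) and quadriceps Myc (2). Titles repeat the same numbers in both muscles. No label says whether a soleus and a quadriceps library of the same number came from 1 animal. Fits and comparisons over both muscles treated all libraries as independent, which was not tested. The p-values measure the spread between these samples. The series also refers to late-life exercise, which is not analysed here.

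The deposited values are a normalised signal per gene: estimated read counts divided by 1 size factor per library, made by the authors. The submitters' processing notes name STAR 2.7.8a, Partek and DESeq2 with no role or order, and name both mm10 and mm39, so no coordinates are given. The division was read from the values: 1 read was worth 0.8311 to 1.161 in quadriceps and 0.8371 to 1.174 in soleus, and 90.9% to 93.4% of values under 300 reads were whole multiples of that step within 0.02 of a read. The median ratio of every library to the gene-wise geometric mean was the same within each table (1.005 in quadriceps, 1.010 in soleus), so a median-ratio scaling equals the deposited one. Estimated depth was 14.2 to 18.4 M reads in quadriceps and 11.1 to 14.9 M in soleus. The tables hold 12366 genes for quadriceps and 13121 for soleus, 12128 of them in both, and every gene listed reached at least 20 reads in some library. Symbols matched a GRCm38.p6 gene table for 12358 and 13114 of them, and that table was used only for names and for which genes are neighbours. Replicates of a group differed by more than sampling noise, so each library was counted once.

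The tests fixed before the data were examined assumed raw counts. Because the values are not counts, limma 3.58.1 in R 4.3.3 was used on log2(value + 1), with a mean-variance trend and robust moderation (statmod 1.5.0), so fold changes of low genes are understated. Genes needed a value of at least 10 in 3 soleus or 2 quadriceps libraries. Each muscle was fitted alone, and the difference between muscles was tested in 1 fit over all 11 libraries. The plan allowed the test of that difference only if both tables held counts, so running it departed from the plan. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Of 40 gene lists fixed before the data were examined, 37 had at least 5 tested members in both muscles. They were tested with camera at a preset correlation of 0.01, adjusted over 74 tests, and again with the correlation estimated. Counts of members adjusted over the list alone are also given. That adjustment was not in the plan. It is easier to pass where many members of a list have a small p, so these counts are description and not a second test. The 3 others, of mitochondrially encoded proteins, neutrophil markers and lymphocyte markers, could not be tested. Values after ± are SD over libraries, or SE where stated.

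Genes are named by a rule fixed in advance: Myc; in each muscle the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes; and from each list up to 4 members with the smallest p in soleus and up to 2 in quadriceps. The text names a part of these, picked after their values were seen. Ribosomal protein genes have many near-identical pseudogenes, so the split of reads among them is uncertain.

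The tests were tried on simulated data drawn from the real means and spreads, with 200 changed genes in each of 5 runs. In soleus 36.0% of 1.5-fold, 62.4% of 2-fold and 83.2% of 4-fold changes were recovered, and 5.43% of calls were false. In quadriceps the shares were 4.20%, 38.6% and 77.5%, and 16.1% of calls were false; for the difference between muscles they were 3.94%, 28.9% and 69.3%, and 21.9% of calls were false. With nothing changed, 4.78% of quadriceps p-values and 4.71% of soleus p-values were under 0.05, and a mean of 6.8 and 0.2 genes was called. False calls in quadriceps and in the difference between muscles were thus above the 5% aimed at. The limma test, which had replaced the planned one, was kept. With a preset correlation camera recovered all 25 lists raised 1.5-fold in each muscle, in a simulation whose genes vary independently, which real genes do not. With an estimated correlation it recovered 23 of 25 in soleus and 0 of 25 in quadriceps, so a list that fails that test in quadriceps was not shown to be unchanged.

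Alternatives were other scalings, limma-voom on estimated reads, other filters and pseudocounts, no robust moderation, a replicate block, 1 fit over all libraries and leaving out each library. DESeq2 and edgeR were planned and not run, since the values are not counts. TMM scaling, the pseudocounts, leaving out soleus Myc replicates 3 and 4 together, the regroupings of libraries for each list and the symbol families were added after seeing the data.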

Results

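The series profiled soleus and quadriceps of mice with an inducible Myc system against age-matched controls. Soleus is a postural hindlimb muscle rich in slow fibres, and quadriceps is mostly fast. There were 3 control and 4 Myc-labelled soleus libraries of 11.1 to 14.9 M estimated reads, and 2 control and 2 Myc-labelled quadriceps libraries of 14.2 to 18.4 M. Levels are normalised read counts, and log2 changes are Myc-labelled minus control.

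The Myc gene row was examined first, as a check of the labels. In soleus it held 37.5 ± 14.6 in controls (SD, n = 3) and 28.4 ± 1.98 in Myc-labelled libraries (SD, n = 4), a log2 change of -0.33 with a 95% interval of -1.18 to 0.52 (limma, adjusted p = 0.69). In quadriceps Myc held 84.7 ± 41.0 in controls and 60.0 ± 37.4 in Myc-labelled libraries (SD, n = 2 each), a log2 change of -0.55 with a 95% interval of -1.90 to 0.80 (limma, adjusted p = 0.93). The row therefore did not identify the Myc-labelled libraries, and every direction below is drawn from the labels.

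**Figure D1:**
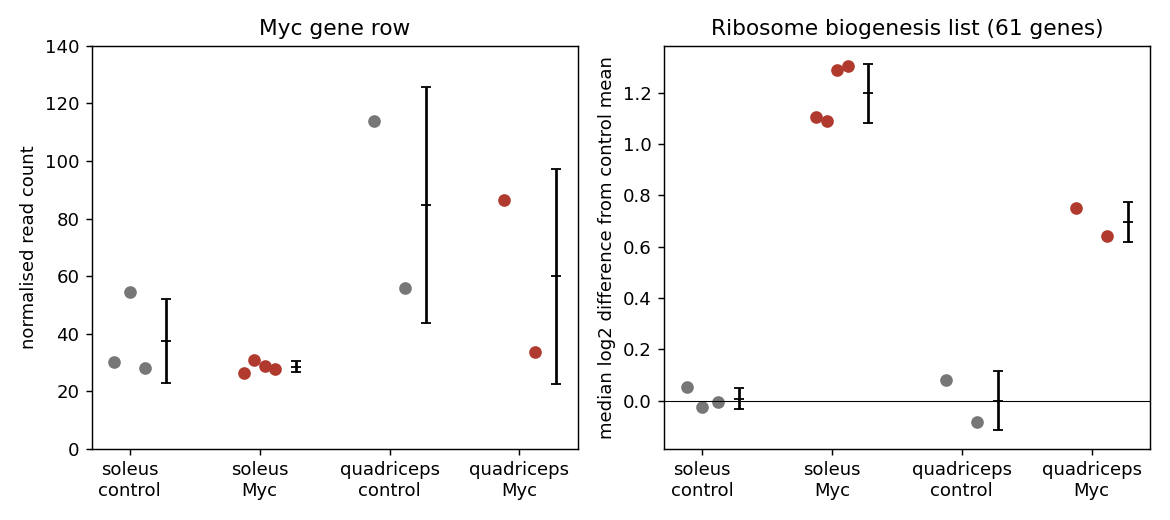
Left, the normalised read count of the Myc row; right, the median log2 difference of 61 ribosome biogenesis genes from the control mean. Each point is 1 library and the bar is mean ± SD; Myc rows overlap between groups, while the ribosome biogenesis level of every Myc-labelled library lies above every control of its muscle.

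In soleus, the comparison asked which transcripts differ after Myc induction. Genes for making ribosomes rose: Gnl3, a nucleolar GTPase, went from 237 ± 33.8 to 1229 ± 115 (log2 change 2.37, SE 0.13), Nhp2 and Dkc1, components of box H/ACA ribonucleoproteins, rose by 2.23 and 2.09, and nucleolin (Ncl) went from 2680 ± 184 to 7588 ± 627. Of 61 ribosome biogenesis genes 56 rose and 0 fell over all genes tested, and 60 rose adjusted over the list alone. Their median log2 change was 1.19 (camera adjusted p = 3.0e-62; adjusted p = 0.138 with an estimated correlation). Across the transcriptome 1184 of 12745 genes changed, 900 higher and 284 lower, and 262 of the higher and 32 of the lower genes changed at least 2-fold. The lower count moved more than the higher one: library-size scaling gave 1078 higher and 179 lower genes, 1 fit over all 11 libraries 833 and 168, and leaving out control replicate 1, 2 or 3 or Myc-labelled replicate 4 left 157, 117, 163 and 154 lower genes. The total was 778 without control replicate 2 and, chosen after seeing the data, 601 (469 higher, 132 lower) without both Myc-labelled replicates 3 and 4.

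Other parts of the protein-making machinery rose with them. Of 20 genes of RNA polymerase I transcription, 10 rose (10 adjusted over the list alone), among them the polymerase subunits Polr1b (log2 change 1.73, SE 0.14) and Polr1a (0.94, SE 0.11). Of 44 translation factors 26 rose (30 adjusted over the list alone), including Eif4a1, an initiation helicase, by 1.30, and Eef1e1 by 1.86. Of 22 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 15 rose (19 adjusted over the list alone), with Vars at 1.31 and Iars at 1.01. Of 78 cytosolic ribosomal protein genes 42 rose (54 adjusted over the list alone), led by Rpl3, from 539 ± 41.2 to 1741 ± 315. None of these lists had a called fall. The adjusted p with an estimated correlation was 0.138 for polymerase I, 0.256 for translation factors, 0.138 for the synthetases and 0.321 for ribosomal proteins.

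Nucleotide and one-carbon synthesis rose in 11 of 34 genes (17 adjusted over the list alone; adjusted p = 0.138 with an estimated correlation). They included Cad, which starts pyrimidine synthesis (146 ± 14.6 to 680 ± 55.9), the CTP synthase Ctps (log2 change 1.89), the purine enzymes Atic (1.78) and Impdh2 (1.57), and Shmt1 (2.38). Of 41 chaperone genes 17 rose and 1 fell (21 and 3 adjusted over the list alone; adjusted p = 0.372 with an estimated correlation), with the chaperonin subunit Cct5 at 1.13 and Hspd1 at 0.91. Mitochondrial ribosomal proteins rose in 13 of 77 genes (14 adjusted over the list alone), with Mrps18b at 0.88 and a list median of 0.16 (adjusted p = 0.650 with an estimated correlation).

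Single genes in soleus are ranked among called, non-predicted genes with a mean of at least 5 CPM and no overlap between groups; some called genes at lower levels had larger changes in both directions. Within that set the largest rises were Dctd, a dCMP deaminase, from 6.43 ± 4.75 to 147 ± 1.52 (log2 change 4.52, SE 0.43), AI506816 from 64.9 ± 15.8 to 1004 ± 341, and Pdxp, a pyridoxal phosphate phosphatase, from 19.9 ± 11.3 to 255 ± 54.2. Arhgdig (log2 change 2.53), Zfp783 (2.52) and the RNA methyltransferase gene Mettl1 (2.52) followed. The largest falls in the set were Mrln, which encodes the calcium-pump inhibitor myoregulin (log2 change -2.00, SE 0.40), Reln (-1.48), the water channel Aqp4 (-1.47), Gch1 (-1.47), Sbk3 (-1.40), Cntfr (-1.29), Igtp (-1.28), Lrrc38 (-1.27), Wnt5b (-1.22) and Gadd45a (-1.17). Reln, Gch1 and Wnt5b lost their call without control replicate 2 (limma, adjusted p = 0.090, 0.15 and 0.12) and in other refits, Gadd45a without control replicate 3 (0.11) and in other refits, Igtp without control replicate 1 (0.10), and Sbk3 in 1 fit over all 11 libraries (0.17). Without both Myc-labelled replicates 3 and 4 the calls of Arhgdig (0.097), Igtp (0.15), Reln (0.054) and Wnt5b (0.052) were lost.

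Lower lists in soleus rested on few called genes. Fast fibre genes had 2 falls in 16 (2 adjusted over the list alone; median -0.38; adjusted p = 0.671 with an estimated correlation), Mylpf (-0.47) and Tpm1 (-0.41). Glycolysis had 2 in 30 (2 adjusted over the list alone; median -0.12; adjusted p = 0.769 with an estimated correlation), of which Slc2a4, the insulin-responsive glucose transporter, fell by 0.43 on the log2 scale. Oxidative phosphorylation had 1 in 75, Ndufa1, and 0 adjusted over the list alone (median -0.11; adjusted p = 0.769 with an estimated correlation). Without control replicate 2 the calls of Mylpf (limma, adjusted p = 0.059), Tpm1 (0.11) and Ndufa1 (0.065) were lost, as they were in 1 fit over all 11 libraries (0.072, 0.23 and 0.066) and without both Myc-labelled replicates 3 and 4 (0.052, 0.055 and 0.13). Myogenic regulators had 1 fall in 22 (1 adjusted over the list alone; median -0.29; adjusted p = 0.260 with an estimated correlation).

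Markers of other cell types also differed between the soleus groups as lists, with hardly any member called. Tendon markers had a median of -0.96 with 0 of 10 called (adjusted p = 0.696 with an estimated correlation), and their level was -2.09 and -1.27 in Myc-labelled replicates 3 and 4 against -0.17 and -0.28 in replicates 1 and 2. The same 2 libraries carried the lower medians of extracellular matrix genes (-0.42, 0 of 32 called; 0.11 and 0.074 in replicates 1 and 2, -0.995 and -0.524 in 3 and 4), erythroid markers (-0.60, 0 of 5; -0.25 and -0.003 against -0.78 and -1.23) and fibroblast markers (-0.29, 1 of 15; -0.13 and 0.10 against -0.73 and -0.27). Without both, these 4 lists stood at -0.20, 0.067, -0.16 and -0.016 and were not called. Schwann cell markers had a median of 0.52 with 0 of 11 called. Adjusted over the list alone, 0 genes were called in each of these 5 lists. With an estimated correlation the adjusted p was 0.774, 0.671, 0.767 and 0.717 in that order.

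The 20 remaining lists did not pass in soleus. Single members did: the polyamine genes Odc1 (log2 change 1.09) and Srm (1.74) rose and Smox fell by 0.83. The amino acid transporters Slc7a1 (1.01) and Slc7a5 (1.47) and the proline enzyme Aldh18a1 (1.62) rose. Aen (0.97), Trp53 (0.86), Ccne2 (1.33) and Mga (0.67) rose as well. Of 20 clock genes 1 rose and 2 fell, Per3 (-0.60) and Bhlhe40 (-0.77), against 1 and 6 adjusted over the list alone. Smox, Per3 and Bhlhe40 lost their call under library-size scaling (limma, adjusted p = 0.050, 0.069 and 0.11), without control replicate 2 (0.22, 0.19 and 0.15) and without both Myc-labelled replicates 3 and 4 (0.055, 0.19 and 0.057). Ccne2 lost its call in the last of these (0.097). Slow fibre genes (median -0.07), 33 exercise and loading response genes and 9 pluripotency genes had 0 calls.

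All 17 list calls in soleus, 9 higher and 8 lower, were lost with an estimated correlation, and camera called 17 or more lists in 8 of the 35 ways to split these 7 libraries into 3 and 4, so the number of lists says little. For ribosome biogenesis, polymerase I, translation factors, aminoacyl-tRNA synthetases, nucleotide synthesis and chaperones no other split gave a camera p as small, and for cytosolic ribosomal proteins 1 other did. Counting the real split, a camera p as small came from 10 splits for fast fibre genes, 13 for oxidative phosphorylation, 16 for tendon markers, 22 for extracellular matrix, 14 for erythroid markers, 19 for fibroblast markers, 15 for Schwann markers, 17 for glycolysis, 6 for mitochondrial ribosomal proteins and 3 for myogenic regulators.

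**Figure D2:**
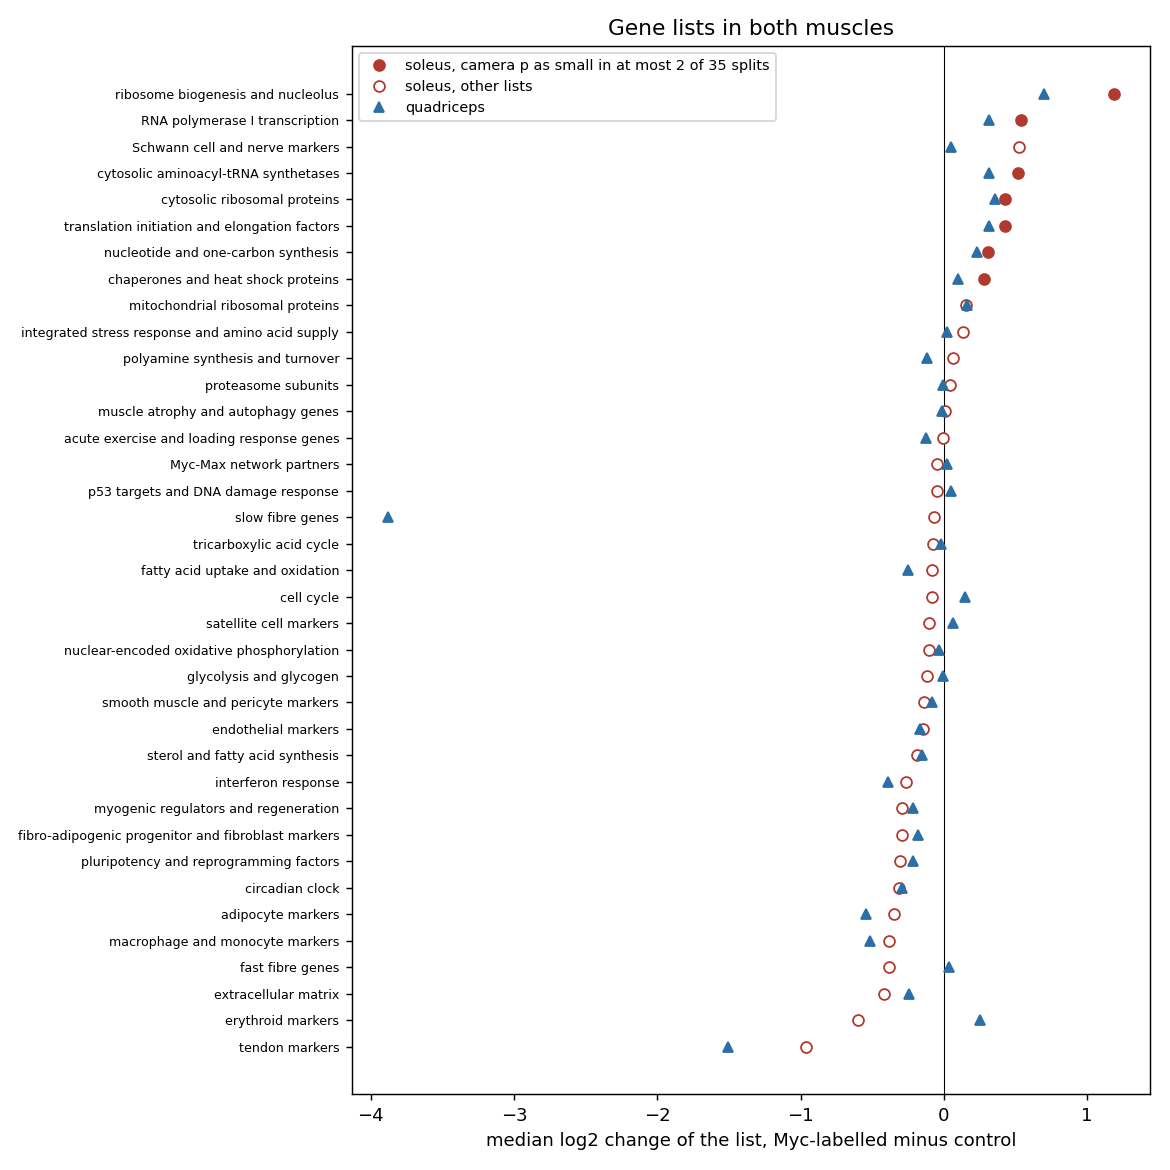
Median log2 change (Myc-labelled minus control) of each of 37 gene lists in soleus (circles) and quadriceps (triangles). Filled circles are the lists whose camera p was matched in at most 2 of the 35 splits of the soleus libraries; ribosome biogenesis lies highest in both muscles and slow fibre genes stand at -3.88 in quadriceps.

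In quadriceps, 1 of 12270 genes changed by limma: AI506816, from 70.1 ± 2.69 to 539 ± 19.9 (SD, n = 2 each; log2 change 2.92, SE 0.21; adjusted p = 0.011). Ribosome biogenesis genes were all above control on average, with a median log2 change of 0.70 over 61 genes; 0 passed over all genes and 39 passed adjusted over the list alone (camera adjusted p = 1.2e-45; adjusted p = 0.321 with an estimated correlation). Gnl3 held 384 ± 74.1 in controls and 994 ± 67.4 in Myc-labelled libraries (adjusted p = 0.20), and Nhp2, Shmt1 and Atic had log2 changes of 1.39, 2.08 and 1.18 (adjusted p = 0.19, 0.19 and 0.23). In 1 fit over all 11 libraries, which borrows the soleus spread, these 4 genes were called (limma, adjusted p = 0.0034, 0.0051, 0.0052 and 0.0034). At an unadjusted p under 0.05 there were 762 genes, 487 higher and 275 lower, where 613.5 would arise by chance. The 2 splits that mix control and Myc-labelled libraries gave 1216 and 211. That count was 1505 with the replicate number as a block and 1121 in 1 fit over all 11 libraries. The call of AI506816 was lost under library-size scaling (log2 change 2.99, SE 0.21, with 5.91 in place of 7.64 degrees of freedom; adjusted p = 0.095), and in simulations of this comparison 16.1% of calls were false and a mean of 6.8 genes was called with nothing changed. The fit over all 11 libraries called 94 genes, 77 higher and 17 lower, while leaving out control replicate 1 or 2 gave 7 and 3, Myc-labelled replicate 1 gave 28, and Myc-labelled replicate 2 gave 208 with the opposite balance, 64 higher and 144 lower.

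Slow fibre genes were the lowest list in quadriceps, with a median log2 change of -3.88 over 15 genes, none called over all genes or adjusted over the list alone (camera adjusted p = 4.7e-16; adjusted p = 0.619 with an estimated correlation). Myh7, the slow myosin heavy chain, held 9731 and 76136 in the control libraries and 174 and 156 in the Myc-labelled ones (adjusted p = 0.60), and Tnnc1, slow troponin C, 1203 and 8658 against 31.9 and 39.5 (adjusted p = 0.62). Both were called in 1 fit over all 11 libraries (limma, adjusted p = 0.012 and 0.017). That fit borrows the soleus spread, which dilutes the difference between the 2 control libraries. Tendon markers stood at -3.44 in Myc-labelled replicate 1 and 0.58 in replicate 2. Camera called 15 lists in quadriceps, 7 higher and 8 lower, and 0 with an estimated correlation; the splits that mix control and Myc-labelled libraries called 19 and 11. Besides ribosome biogenesis, the higher lists were ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, mitochondrial ribosomal proteins, nucleotide synthesis and polymerase I, with estimated-correlation adjusted p = 0.671, 0.619, 0.634, 0.619, 0.321 and 0.619. The other lower lists were fatty acid oxidation, interferon response, clock, extracellular matrix, macrophage, adipocyte and tendon genes, with estimated-correlation adjusted p = 0.774, 0.767, 0.619, 0.814, 0.774, 0.769 and 0.769. Without Myc-labelled replicate 1 the medians turned for fatty acid oxidation (0.011), extracellular matrix (0.21), macrophage (0.16) and tendon genes (0.58), and without Myc-labelled replicate 2 for adipocyte genes (0.038).

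Between muscles, the genes that rose in soleus lay mostly above control in quadriceps as well. Of 896 soleus-higher genes tested in both, 869 (97.0%) had a positive log2 change in quadriceps, with a median of 0.41 against 0.74 in soleus, and 265 of 282 soleus-lower genes (94.0%) had a negative one. When the quadriceps libraries were split so that control and Myc-labelled were mixed, the shares were 65.2% and 52.1% for the higher genes and 53.2% and 40.8% for the lower ones. The direction of each mixed split was set so that most of the higher genes were positive, and the share for the lower genes follows that choice. Only 3 splits exist, the real one included, so they cannot exclude chance. At an unadjusted p under 0.05 in both muscles 399 genes were higher in both, where 66.1 would be shared by chance, and 106 were lower in both, against 24.5. At the adjusted threshold the muscles shared only AI506816 (Fisher's exact test, one-sided, p = 0.075). With 1 gene called in quadriceps that p is the smallest this test could give, so it cannot decide whether the sharing exceeds chance. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.46 and Spearman's rho = 0.51.

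**Figure D3:**
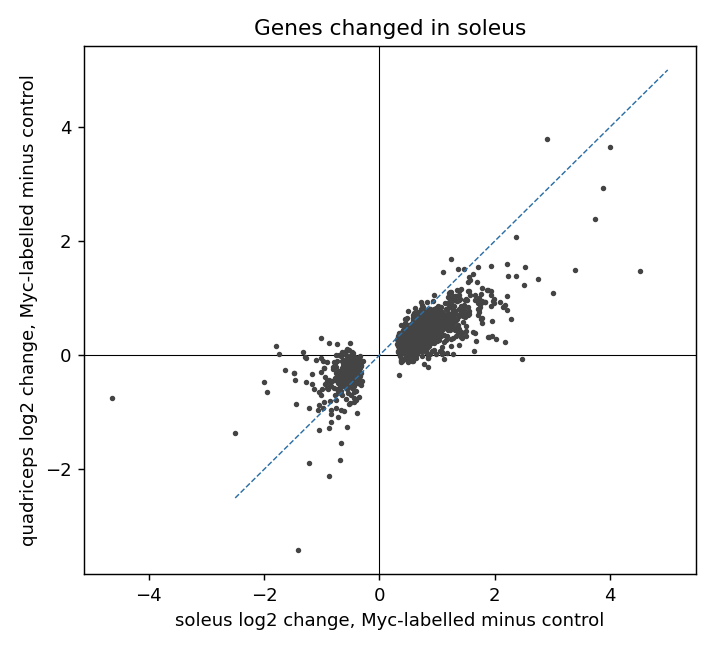
Log2 change (Myc-labelled minus control) in quadriceps against soleus for the genes called in soleus and tested in both; each point is 1 gene and the dashed line marks equal change. Of the 896 genes higher in soleus, 869 lie above 0 in quadriceps.

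The change in Myc-labelled libraries differed between muscles for 0 of 11971 genes by limma, with 381 at an unadjusted p under 0.05 where 598.6 would arise by chance, 0 by limma-voom and 4 without robust moderation. Without quadriceps control replicate 1, control replicate 2 or Myc-labelled replicate 2 there were 22, 8 and 6. As lists, 11 of 37 differed, among them ribosome biogenesis with a median of 0.48 more in soleus (camera adjusted p = 2.1e-27; adjusted p = 0.122 with an estimated correlation) and slow fibre genes with 3.83 (adjusted p = 0.122 with an estimated correlation). With an estimated correlation 0 of the 11 held. The plan had reserved this comparison between muscles for counts, so it was run outside the plan.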

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

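The tests of exchanged labels, of too few reads on the Myc row, of slow fibre genes and of the deposited scaling were chosen after the result they bear on was seen, though the fits that give the Myc bounds and the library-size scaling were planned.

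Of 89 sets of 4 soleus Myc-labelled values examined, over 52 genes and 37 lists, 2 held a library far from the others; chance flags about 1 in 20. AI506816 stood at 495 in replicate 3 against 1142 to 1214 in the others (gap over range 0.93), and Arhgdig at 185 in replicate 4 against 92.5 to 101 (0.87). For genes the gap over range was computed on log2(value + 1), not on the counts printed here.

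The effect differed between muscles for 11 lists by camera, all lost with an estimated correlation. The median soleus minus quadriceps log2 difference was 3.83 for slow fibre genes, 0.48 for ribosome biogenesis, 0.24 for chaperones, 0.16 for aminoacyl-tRNA synthetases, 0.25 for nucleotide synthesis, 0.093 for translation factors, 0.20 for polymerase I and 0.18 for fatty acid oxidation. It was -0.40 for fast fibre genes, -0.83 for erythroid markers and -0.074 for oxidative phosphorylation.

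The Myc row was not higher in libraries labelled Myc. An exchange of single libraries between control and Myc is argued against by the ribosome biogenesis level. Its smaller gap between the lowest Myc-labelled and the highest control library was 0.56 log2 units, in quadriceps, above the within-group SD of 0.12. An exchange of all labels would leave gaps of the same size. Only their direction speaks against it, and only if Myc raises these genes, which was assumed and not tested. Too few reads to see a 2-fold rise is argued against in soleus by the upper 95% bound of 0.52. The upper bound of 0.80 in quadriceps rests on 2 libraries a group and cannot decide this. It lay under a 2-fold rise because the estimate itself was -0.55, and that estimate turned to 0.12 without Myc-labelled replicate 2. It stays open, and was not tested, whether transgene reads were counted on another row or whether the transcript had fallen by 12 hours after withdrawal.

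Slow fibre genes were lower in Myc-labelled quadriceps. A fall in Myc-labelled muscle of both kinds is argued against by soleus, where the list median was -0.072 with a between-library SD of up to 0.16. A different share of slow-fibre muscle in each sample remains a candidate explanation, since the 2 control libraries differed from each other by a median of 2.85 log2 units over these 15 genes, against 0.26 over all genes. A response limited to quadriceps also stays open with 2 libraries a group.

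The count of 1184 genes in soleus was matched by 1 of the 35 splits of the libraries, the real one, and the highest of the others called 22. That share of 0.029 is the smallest that 35 splits can give, so chance is argued against and not excluded. For the 17 lists the splits do not argue against chance, as 8 of 35 called as many and the highest other called 24. The deposited scaling as the whole cause is argued against, since under 3 other scalings at least 95.6% of the median log2 change of the higher genes and 91.8% of that of the lower genes was left. Library-size scaling shifted every called gene by about 0.046 and ended 106 lower calls near the threshold (median log2 change -0.50 to -0.45, SE 0.143 to 0.148, adjusted p 0.041 to 0.068); a change common to all transcripts would show under none of these scalings. A strain difference between the groups cannot be told apart from an effect of Myc. Changed genes neighboured genes changed the same way 1.12 times as often as under shuffled positions, with a shuffling SD of 0.11 (permutation p = 0.16). The ratio lay under 1.2, the bound set beforehand for arguing against a strain difference, but by less than that SD. The bound set beforehand held no such margin, and no conclusion is drawn.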

How the results depend on the processing

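TMM scaling, the pseudocounts and leaving out soleus Myc replicates 3 and 4 together were chosen after seeing the data. The soleus count of 1184 stayed within 1.5 times under every scaling, filter, pseudocount and tool tried, and fell to 294 with a log2 change of at least 1; leaving out 1 library gave 778 (without control replicate 2) to 1015, and leaving out Myc replicates 3 and 4 together 601. Its 284 lower genes moved more, to 179 under library-size scaling, 362 under upper-quartile scaling, 168 in 1 fit over all libraries and 117 to 244 without 1 library, where the 900 higher genes became 1078, 819, 833 and 661 to 789. Of 51 called soleus genes named, 37 kept their call in every refit, 14 lost it in some and 0 reversed. The quadriceps count of 1 became 0 under library-size scaling and 94 in 1 fit over all libraries; leaving out 1 library, which assumes that the lone sample varies like the others, gave 3 to 208, the latter without Myc replicate 2 and with 144 of them lower (7 without control replicate 1, 28 without Myc replicate 1). The difference between muscles gave 4 genes without robust moderation and 0 to 22 without 1 library.

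Lists called went from 17 to 0 with an estimated correlation and 8 by fry in soleus (16 to 18 without 1 library), and from 15 to 0 and 1 in quadriceps (12 to 21). Shared calls went from 1 to 2 at an adjusted p under 0.1 and to 505 at an unadjusted p under 0.05, and were 1 to 57 without 1 library. The log2 change of Myc was -0.50 to -0.03 in soleus and -1.22 to 0.12 in quadriceps without 1 library, positive without quadriceps Myc replicate 2. Leaving out 1 quadriceps library put the median of fatty acid oxidation at -0.54 to 0.011, extracellular matrix at -0.66 to 0.21, tendon markers at -3.44 to 0.58 and adipocyte markers at -1.56 to 0.038, and that of macrophage markers at up to 0.16. The highest values came without Myc replicate 1, and for adipocyte markers without Myc replicate 2; without control replicate 2 (-0.13) their camera direction turned as well. In soleus the median of extracellular matrix genes turned to 0.067 without Myc replicates 3 and 4. The cause was not tested.

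In soleus replicate numbers were not seen to pair the samples: same-numbered deviations correlated at 0.00, 0.08 and 0.14, and other pairs at -0.20 to 0.21. In quadriceps the values were 0.14 for same-numbered and -0.14 for other pairs. With 2 libraries a group these are 1 value mirrored, which cannot decide. With the replicate number as a block, soleus called 1216 genes and quadriceps 4. At an unadjusted p under 0.05 quadriceps then had 1505 genes in place of 762. DESeq2 was not run, since the values are not counts, and a median-ratio scaling equals the deposited one. Depth sets which genes could be tested, 12745 of 13121 listed in soleus and 12270 of 12366 in quadriceps.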

Other observations

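The tests of symbol families in this part were chosen after seeing the data. Outside the fixed lists, 17 families defined by gene symbol were tested with camera in both muscles, 34 tests in all. In soleus, 6 of 17 mitochondrial aminoacyl-tRNA synthetases rose, Ears2 and Vars2 among them (median log2 change 0.50), 5 of 10 RNA polymerase III subunits, with Polr3g and Polr3d (0.50), 4 of 10 RNA exosome genes (0.50), 9 of 30 further DEAD-box helicases (0.33), 8 of 24 mitochondrial import genes, with Tomm70a and Timm10 (0.26), 7 of 20 importins and exportins (0.13), 6 of 21 tRNA and rRNA methyltransferases (0.33) and 4 of 7 arginine methyltransferases, led by Prmt3 (0.95). Nuclear pore genes (2 of 19, 0.30) and snRNP genes (2 of 12, 0.34) were higher too, and MHC genes lower (2 of 20, -0.19). These 10 higher families and 1 lower family passed in soleus, and 0 did with an estimated correlation (smallest adjusted p = 0.075). Potassium channels, mitochondrial carriers, zinc finger, F-box, Rab and histone genes did not pass in soleus. In quadriceps the same 10 families were higher, with 0 genes called, and histone genes lower; 0 held with an estimated correlation.

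Of the 2 paralogs of ribosomal protein L3, Rpl3 rose by 1.67 on the log2 scale in soleus, and Rpl3l, the striated muscle form, held 5872 ± 341 in controls and 4709 ± 612 in Myc-labelled libraries (log2 change -0.33, adjusted p = 0.068). The Rn45s row, the ribosomal RNA precursor, held 690 ± 187 and 1239 ± 277 in soleus (log2 change 0.86, adjusted p = 0.051) and 674 ± 269 and 621 ± 89.3 in quadriceps. The Rn18s row, 18S ribosomal RNA, took 3.11% and 4.32% of the signal in quadriceps controls and 2.03% and 2.01% in Myc-labelled libraries (log2 change -0.92, adjusted p = 0.65, and 0.046 in 1 fit over all 11 libraries), against 0.29% to 0.45% across soleus. Whether the removal of ribosomal RNA or the quality of the libraries differed between the quadriceps groups was not tested and stays open. H2-T10 held 3.90 ± 3.88 in quadriceps controls and 129 ± 8.17 in Myc-labelled libraries (adjusted p = 0.23). Rpl3l, Rn45s, Rn18s and H2-T10 were chosen after their values were seen, from planned fits, and did not pass in the fits of single muscles given here.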
